A study of Glycine max with 8 samples.

How the data were processed

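RNA sequencing libraries of mature leaves from 2 soybean lines, WT and OX5, were compared, with 4 libraries per line. Per the labels, RNA was extracted with Trizol, its purity and integrity were checked, and libraries were made with a VAHTS Universal V6 kit for Illumina sequencing. The deposited file is 1 table of FPKM (fragments per kilobase of gene, scaled to the depth of the library) with 1 column per library, made by the authors, and no column of per-sample values was left unused. The submitters' processing notes name CASAVA, Bowtie2 2.2.3, HISAT2 2.1.0, TopHat2 and HTSeq 0.6.0, without saying which step each performed. The genome build, the strand setting and the treatment of reads shared between gene copies are not given in the sources used here. The gene IDs carry the suffix Wm82.a4.v1, and chromosome numbers were read from the IDs. No coordinates were used.

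The table lists 31785 genes, of which 30976 have a chromosome in their ID, 75 lie on scaffolds and 734 are numbered outside the annotation. A single row names no gene and holds no value; it was left out. Every listed gene had at least 22 recovered reads over all libraries. The FPKM values have 4 decimals and are whole multiples of what 1 read is worth at each gene, which let the reads be recovered. Whole reads came out for 100% of the 31785 genes, with a 99th percentile distance of 0.0054 reads from a whole number. When each value was changed by up to 2%, 3.10% of genes were still solved, and 0% with counts no larger than those of the deposited values. On simulated data, 99.6% of 31785 genes had every count exact. The recovered reads numbered 18914787, 18910088, 18768431 and 19156866 in WT replicates 1 to 4 and 18143853, 19139497, 17536942 and 17545271 in OX5 replicates 1 to 4. These totals cover the listed genes only. Recovered reads were used for depth, for loci at 0 and for an added fit, and the intervals and limits from them cover counting error only.

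Before the data were examined, the groups, the test, the thresholds, 17 alternative fits and a stricter adjusted p of 0.01 were fixed. The main test was limma 3.58.1 (R 4.3.3) with a trend in the variance on log2(FPKM + 1), for the 30424 genes with a mean of at least 0.5 FPKM over all 8 libraries, with Benjamini-Hochberg adjustment and a threshold of 0.05. A second count took changes of at least 2-fold, a log2 fold change of 1. The alternatives were a pseudocount of 0.1, no filter, a mean of at least 2 FPKM, quantile normalization, median-ratio size factors, rescaling to a sum of 1000000, robust empirical Bayes, library quality weights, the replicate number as a block, and leaving out each of the 8 libraries. Chosen after seeing the data were 3 more fits, namely limma-voom on the recovered reads and fits without OX5 replicates 1 and 2 or without 3 and 4. The tests of neighbouring loci, of chromosomes and of loci at 0 reads were also chosen after seeing the data.

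In simulated reads for the comparison of OX5 against WT, over 30424 genes with independent noise, the test recovered 48 of 100 genes changed 2-fold and 85 of 100 changed 4-fold, with 11 false calls among 144. With no simulated change it made 0 calls. The simulation holds no factor shared between libraries of a line. Its changed genes were drawn only from genes above a minimum mean read count, so recall at genes with few reads was not measured.

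Neighbouring loci were successive tested loci on a chromosome in order of ID, and calls were permuted 100000 times within chromosomes. The spread over chromosomes was tested with 100000 random draws of the same number of loci. A locus was counted as present in 1 line when it had 0 reads in every library of the other line and at least 10 reads in each of its own. Where a line had 0 reads, folds were taken against 3 reads per library. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and numba 0.67.0 was used.

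The files do not pair gene IDs with names, and the RefSeq gene table holds no such IDs. The 35 gene lists and 20 loci chosen by description or published name were therefore not used, and no list test was run. The rule for named genes was to take the largest rises and falls among genes past the adjusted threshold with values that do not overlap between lines and a mean of at least 5 FPKM in the higher line. It was limited to 2 rises and 2 falls, without its condition on descriptions.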

Results

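Messenger RNA abundance was measured by RNA sequencing in mature soybean (Glycine max) leaves of 2 lines, wild type (WT) and the line labelled OX5. The plants were grown with sufficient phosphorus and sampled at R6, the full-seed stage of soybean reproductive growth. Each line had 4 libraries, and the comparison asks which leaf transcripts differ between OX5 and WT. The gene altered in OX5 is not given in the labels, so no gene was treated as its target. The labels do not say whether the 4 libraries of a line came from separate plants, and p-values then measure only the spread between these samples, which may be technical. Whole reads recovered from the FPKM steps numbered 18768431 to 19156866 per library in WT and 17536942 to 19139497 per library in OX5. The number of genes at 1 FPKM or more was 27379 ± 187 in WT and 27536 ± 746 in OX5 (SD, n = 4 each). No pair of libraries agreed within counting noise, as a library deposited again would, so each of the 8 was counted once; this does not show that they came from separate plants.

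The OX5 libraries fell into pairs, replicates 1 and 2 and replicates 3 and 4. Across 30424 genes, log2 values correlated with a median r of 0.966 between WT libraries, 0.930 between OX5 libraries and 0.927 between the lines, where genes are not independent replicates. OX5 replicates 1 and 2 correlated at 0.982 with each other, and OX5 replicates 3 and 4 at 0.978, while the lowest r within OX5 was 0.90. The first principal component carried 44.8% of the variance and placed OX5 replicates 1 and 2 at 69.8 and 88.6, OX5 replicates 3 and 4 at −12.6 and −19.8, and the WT libraries between −40.5 and −23.2. On the second component, with 20.6%, OX5 replicates 3 and 4 stood at 34.4 and 68.4, and every WT library was below −17. The third component, with 17%, placed WT replicates 1 and 4 at −55.4 and 56.5 and every OX5 library between −4.45 and −1.15. The median SD of log2 values between replicates was 0.210 in WT and 0.262 in OX5.

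**Figure D1:**
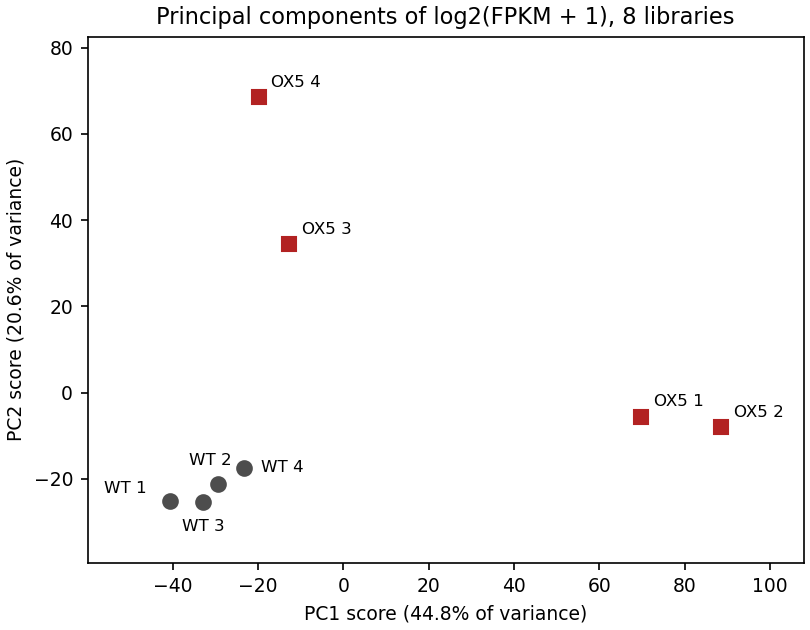
Scores of the 8 libraries on the first and second principal components of log2(FPKM + 1), with the share of variance on each axis label, WT as circles and OX5 as squares. The 4 WT libraries sit together on these components, OX5 replicates 1 and 2 lie at 69.8 and 88.6 on the first component, and OX5 replicates 3 and 4 lie at 34.4 and 68.4 on the second.

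In OX5 leaves, 421 genes rose and 308 fell relative to WT, of 30424 genes tested. Among changed genes with no overlap between the lines and at least 5 FPKM in the higher line, the largest rise on the log2(FPKM + 1) scale was that of the chromosome 19 locus Glyma.19G026600.Wm82.a4.v1, from 1.28 ± 0.767 FPKM in WT to 129 ± 31 FPKM in OX5 (SD, n = 4 each), a 100.7-fold difference of the means. The chromosome 17 locus Glyma.17G235366.Wm82.a4.v1 had no read in any WT library and 19.4 ± 3.47 FPKM in OX5 (SD, n = 4). On the same scale and by the same rule, the largest falls were at Glyma.12G087200.Wm82.a4.v1 on chromosome 12, from 30.4 ± 18.3 to 3.01 ± 3.46 FPKM, and at Glyma.09G163900.Wm82.a4.v1 on chromosome 9, from 38.7 ± 6.01 to 6.44 ± 4.40 FPKM (SD, n = 4 each). The ranking holds on that scale only and is another by the ratio of the means. The calls are limma's at a Benjamini-Hochberg adjusted p under 0.05, and fold changes are on the log2(FPKM + 1) scale, which understates the change of low genes.

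Risen genes had a median log2 fold change of 0.93 (interquartile range 0.72 to 1.21), and fallen genes one of −1.11 (interquartile range −1.45 to −0.88). The change was at least 2-fold for 369 genes, of which 176 rose and 193 fell. The risen genes together made up 0.934% to 1.02% of all FPKM in the WT libraries and 1.67% to 2.09% in the OX5 libraries. The fallen genes made up 1.18% to 1.29% in WT and 0.461% to 0.610% in OX5. All 421 risen genes and 307 of the 308 fallen genes had WT and OX5 values that did not overlap. Non-overlap was seen in 14.2% of all genes tested. Chance gives 2.86% if all libraries are independent, and more if OX5 libraries vary together in pairs. The independence of the OX5 libraries is not known, so an excess over chance is not established. By mean abundance, the share of genes that rose was 0.546% at 0.5 to 2 FPKM, 1.30% at 2 to 10 FPKM, 2.00% at 10 to 50 FPKM and 1.43% at 50 FPKM and above, and the share that fell was 0.820%, 1.06%, 1.06% and 1.03%.

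The balance of rises and falls moved with the scaling. Of the 729 calls, 57.8% were rises, and after rescaling each library to a sum of 1000000, 246 of 561 calls (43.9%) were rises. Rises stayed the majority with quantile normalization, at 550 of 988 calls (55.7%), and with median-ratio size factors, at 495 of 945 (52.4%). Among changes of at least 2-fold, rises made up 47.7% as deposited and 38.4% after the rescaling to a sum. With quantile normalization they made up 47.3% of these, and with median-ratio size factors 45.5%. The number of calls also moved when 1 library was left out. Each such fit has 1 library fewer than the main fit. Against the main fit, lost power and the weight of the library itself therefore cannot be told apart. Between these fits the number of libraries is equal, so the differences among them depend on which library was left out. The number of calls was 58 without WT replicate 3, 160 without OX5 replicate 2 and 188 without WT replicate 2. It was 334 without WT replicate 4, 392 without OX5 replicate 4 and 428 without WT replicate 1. Without OX5 replicate 1, 52 genes rose and 49 fell, and without OX5 replicate 3 the number was 761. Rises were the minority without WT replicate 1, at 209 of 428 calls, and without OX5 replicate 2, at 77 of 160. They were the majority in every other fit with 1 library left out.

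**Figure D2:**
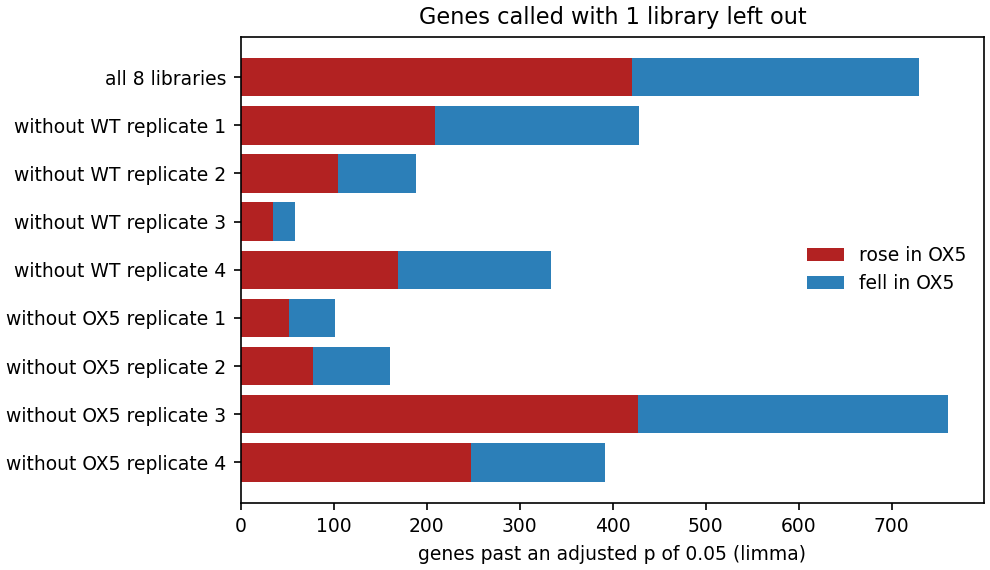
Number of genes past a limma adjusted p of 0.05 with all 8 libraries and with each library left out in turn, divided into genes that rose (red) and fell (blue) in OX5. The count was 729 with all libraries and lay between 58, without WT replicate 3, and 761, without OX5 replicate 3.

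Each library was placed between the lines, with 0 at the WT mean and 1 at the OX5 mean of the other 7 libraries, over the genes called without it. These sets differ between libraries, from 58 to 761 genes, so the positions are not measured over the same genes. OX5 replicates 1 and 2 had median positions of 0.977 and 1.1. OX5 replicate 3 had 0.60 and OX5 replicate 4 had 0.836. The WT libraries lay between 0.041 and 0.247. With OX5 replicates 1 and 2 both left out, 242 genes were called, and with OX5 replicates 3 and 4 both left out, 5503 were called; both fits were chosen after the libraries had been seen.

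Glyma.19G026600.Wm82.a4.v1 had 0.521, 0.812, 1.55 and 2.23 FPKM in WT replicates 1 to 4, from 43 to 186 reads. It had 170, 129, 121 and 95.3 FPKM in OX5 replicates 1 to 4, from 7287 to 13454 reads. Its log2 fold change was 5.86 (SE 0.26, limma adjusted p = 2.1e-05). Glyma.17G235366.Wm82.a4.v1 had 18.3, 18.8, 24.3 and 16.2 FPKM in OX5 replicates 1 to 4, from 30 to 45 reads. A count of 3 reads in a library corresponded to 1.57 FPKM at this locus, so OX5 was at least 12.3-fold higher (limma adjusted p = 6.7e-06), a limit that covers counting error only. Both rises passed the adjusted threshold in all 20 alternative fits.

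Glyma.12G087200.Wm82.a4.v1 had 52.6, 8.87, 34.7 and 25.2 FPKM in WT replicates 1 to 4 and 0.727, 0.485, 7.95 and 2.90 FPKM in OX5 replicates 1 to 4. Its log2 fold change was −3.11 (SE 0.65, limma adjusted p = 0.047), and it passed the threshold in 9 of the 20 alternative fits, with a highest adjusted p of 0.147. The log2 fold change ran from −2.17 without OX5 replicates 1 and 2 to −4.05 without OX5 replicates 3 and 4, and apart from the former, the fits that lost the call had −3.93 to −2.76. Glyma.09G163900.Wm82.a4.v1 had 35.7, 46.6, 32.7 and 39.8 FPKM in WT replicates 1 to 4 and 3.85, 1.57, 10.3 and 10.1 FPKM in OX5 replicates 1 to 4. Its log2 fold change was −2.65 (SE 0.44, limma adjusted p = 0.025), and it passed in 15 of the 20, with a highest adjusted p of 0.0868. The log2 fold change ran from −1.82 without OX5 replicates 1 and 2 to −3.48 without OX5 replicates 3 and 4, and the fits that lost the call had −2.72 to −2.52. The tested locus before it on chromosome 9 also fell, with a log2 fold change of −2.34 (limma adjusted p = 0.021). At both named falls, the 2 lowest OX5 libraries were replicates 1 and 2, which stand apart on the first principal component.

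**Figure D3:**
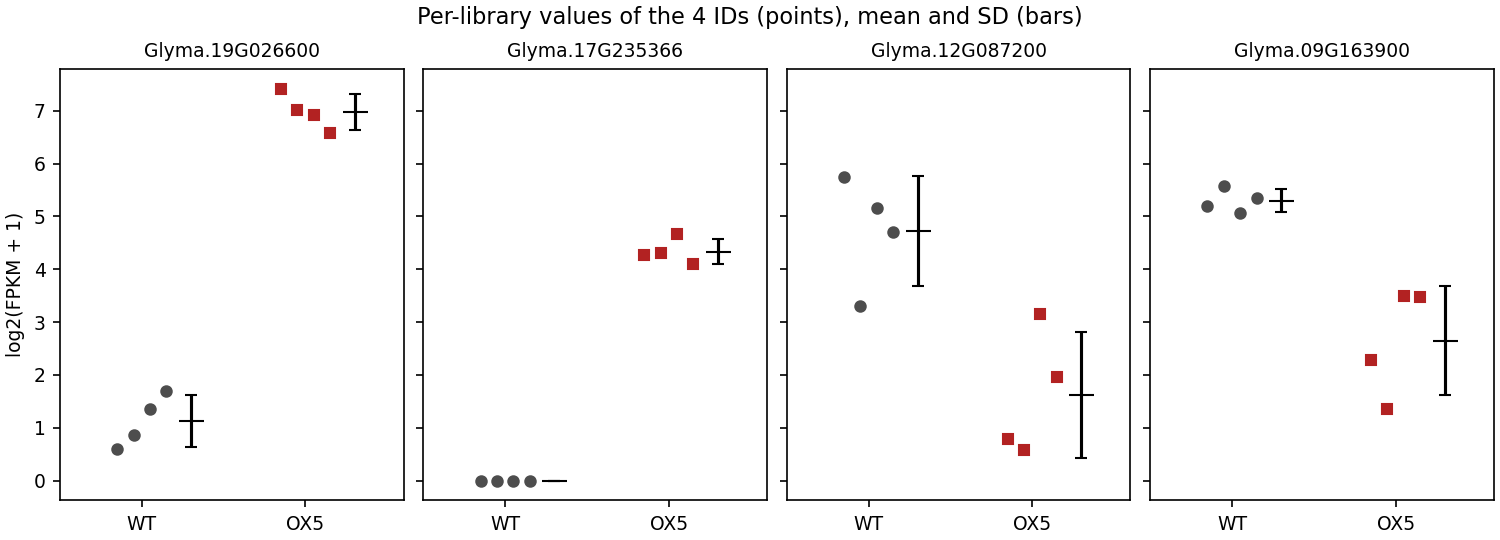
log2(FPKM + 1) of the 4 named loci in each library, with WT as circles and OX5 as squares in order of replicate number, and bars for the mean and SD of the 4 log2 values. Glyma.19G026600 and Glyma.17G235366 were higher in every OX5 library than in every WT library, and Glyma.12G087200 and Glyma.09G163900 were lower in every OX5 library.

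A set of 9 loci had no read in any WT library and at least 10 reads in every OX5 library. Their counts in OX5 ran from 26 to 204 reads per locus and library, and they summed to between 732 and 835 reads per OX5 library. No locus showed the reverse, with no read in OX5 and at least 10 reads in every WT library. With a minimum of 1 read, 9 loci were at 0 in every WT library and 1 locus was at 0 in every OX5 library. Of the 9, 3 were successive tested loci on chromosome 17, 1 was on chromosome 20, and 5 were numbered outside the annotation and have no chromosome in their ID. The 3 loci on chromosome 17, which include Glyma.17G235366.Wm82.a4.v1, had 9.70 to 24.3 FPKM in the OX5 libraries. Of the 4 tested loci to each side of them, 0 of 8 passed the limma test, with a lowest adjusted p of 0.0696. Among the 10 largest rises, 5 loci were at 0 in every WT library.

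**Figure D4:**
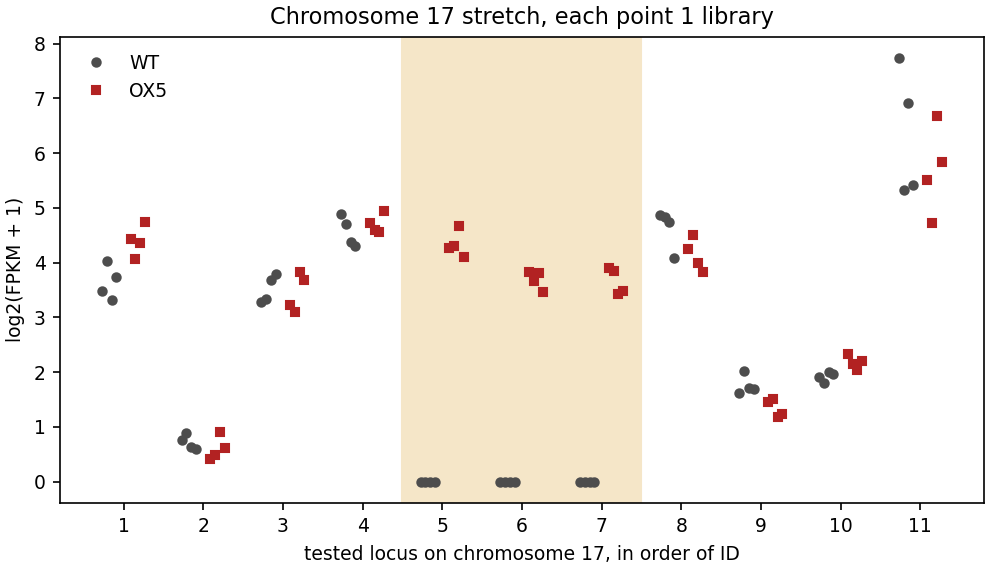
log2(FPKM + 1) at 11 successive tested loci on chromosome 17 in order of ID, each point 1 library, with WT as circles and OX5 as squares. The 3 shaded loci are at 0 in all 4 WT libraries and at 9.70 to 24.3 FPKM in the OX5 libraries, and both lines have reads at the 4 loci to each side.

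Neighbouring loci changed in the same direction more often than chance gives, although most changed loci had no such neighbour. Of 29635 tested loci with a chromosome in their ID, 406 rose (1.37%) and 303 fell (1.02%). There were 31 pairs of successive loci with the same direction, where permutation of the calls within chromosomes gave 8.76 on average (95% of permutations between 4 and 15). The one-sided permutation p was 1e-05, the smallest that 100000 permutations can give (adjusted p = 4e-05 over 4 tests), and 29 pairs lay outside the chromosome 17 stretch. The runs held 60 of the 709 changed loci (8.46%). The longest runs were 3 risen loci on chromosome 17 and 3 fallen loci on chromosome 9. Pairs of opposite direction numbered 10, where permutation gave 8.30 (permutation p = 0.317, adjusted p = 0.357). With 1 library left out, the same-direction pairs numbered 2 to 25, as the number of calls moved too. There were 2 without WT replicate 3 (permutation p = 0.00101), 3 without OX5 replicate 1 (permutation p = 0.00048) and 2 without OX5 replicate 2 (permutation p = 0.0556).

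Rises and falls were found on all 20 chromosomes. The share of tested loci that rose was highest on chromosome 20, at 27 of 1346 (2.01%, 95% Wilson interval 1.38% to 2.90%), and lowest on chromosome 13, at 16 of 2088 (0.766%, 0.472% to 1.24%). The share that fell was highest on chromosome 17, at 25 of 1476 (1.69%, 1.15% to 2.49%), and lowest on chromosome 18, at 8 of 1450 (0.552%, 0.280% to 1.08%). A permutation test of the spread over chromosomes gave p = 0.357 for rises (adjusted p = 0.357) and p = 0.067 for falls (adjusted p = 0.134). For falls, the unadjusted p was under 0.05 in 8 of the 20 alternative fits, so the call rests on the setting.

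The share of rises at loci numbered outside the annotation could not be told from that of annotated genes. Of 720 such loci tested, 14 rose (1.94%), against 407 of 29704 annotated genes (1.37%). The odds ratio was 1.43 with a 95% interval of 0.769 to 2.44 (Fisher's exact p = 0.194, adjusted p = 0.581 over 3 tests). Of the same 720 loci, 5 fell (0.694%), against 303 annotated genes (1.02%; Fisher's exact p = 0.568, adjusted p = 0.622).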

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

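The tests of depth, of exchanged libraries, of a differing stretch of DNA and of other splits were chosen only after the results were seen; that of gene length was not.

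The summed FPKM of OX5 replicate 4 was 623720, far above the other OX5 libraries, which lay between 594118 and 597668. Among 22 groups of 4 values examined for a lone extreme value, this was the 1 that stood out, and chance gives about 1 in 20. In that library the 100 most abundant genes held 21.3% of all FPKM, against 16.5% to 18.2% in the other OX5 libraries.

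OX5 replicates 1 and 2 stood apart on the first principal component, at 69.8 and 88.6, while OX5 replicates 3 and 4 lay near WT on it. Sequencing depth is argued against, since both of these 2 libraries, with 18143853 and 19139497 reads, lay inside the 17536942 to 19156866 reads of the other 6. A trend with gene length, as RNA breakdown could give, is argued against by a Spearman rho of −0.047 across genes. It was taken between the component's weights and the length implied by the FPKM steps. RNA breakdown without such a trend stays open. An exchange of libraries between the lines is argued against as well, since no other split of the 8 libraries called more than 1 gene, against 729 for the labelled lines. Also open is a difference between plants, positions, leaf ages or harvest times within OX5, or a technical one in how the libraries were made. None of these was tested. OX5 replicates 1 and 2 correlated at 0.982 and OX5 replicates 3 and 4 at 0.978, above the highest r between WT libraries, 0.974. It is therefore not known whether OX5 holds 4 independent samples.

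A set of 9 loci had no read in WT and 26 to 204 reads per locus in each OX5 library, and 3 of the 4 with a known chromosome were successive on chromosome 17. Of the 35 splits of the libraries, only the real one gave as many such loci, and the highest other split gave 2. This cannot exclude chance, because a locus that meets the rule in 1 split cannot meet it in another. The rule was also chosen after seeing the data. A stretch of DNA that differs between the lines may account for the chromosome 17 loci, a hypothesis that their adjacency prompted. Random draws of 4 loci gave as many neighbouring pairs with a permutation p of 1e-05, the smallest that permutations can give, which describes that adjacency and is no separate support. The explanation stays open, because no sequence was used here.

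The locus with the largest rise on the log2(FPKM + 1) scale, Glyma.19G026600.Wm82.a4.v1, was at 0.405%, 0.631%, 1.21% and 1.73% of its OX5 mean in WT replicates 1 to 4.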

How the results depend on the processing

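Fits with limma-voom, fits without a pair of OX5 libraries and all alternatives for neighbouring loci and loci at 0 reads were chosen after seeing the data. Against 729 calls, of which 369 were at least 2-fold, library quality weights gave 9504 and 2164, and the adjusted p of 0.01 gave 57. Limma-voom on recovered reads gave 435 calls. Without OX5 replicates 1 and 2 the counts were 242 and 208, and without OX5 replicates 3 and 4 they were 5503 and 2444. Leaving out 1 library gave 58 to 761 calls and 58 to 496 of at least 2-fold, lowest without WT replicate 3 and highest without OX5 replicate 3. The 7 other fits of filter, pseudocount, scaling or variance stayed between 561 and 988 calls and between 325 and 436 of at least 2-fold. No called gene changed direction, which values that do not overlap between the lines leave little room for. The cause of these differences was not tested.

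With the replicate number as a block, 56 genes were called, all at least 2-fold. Deviations of libraries with the same number correlated at −0.06, 0.07, 0.13 and −0.06 across genes, and those with different numbers at −0.17 to 0.11. Not every library correlated best with its own number. These values show no clear pairing of the samples by number, but a weak one cannot be excluded.

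Same-direction pairs of neighbouring loci passed in 19 of 20 fits, and numbered 2 to 25 when 1 library was left out. The replicate block and the fit without WT replicate 3 passed with 2 pairs, as many as the chromosome 17 stretch alone can give. Pairs outside that stretch were counted for the main fit only. Without OX5 replicate 2 there were 2, with a permutation p of 0.0556. Loci at 0 reads in WT numbered 9 to 11 in the 9 alternatives, each of which relaxes the rule and so cannot lower the count. The spread of falls over chromosomes passed in 8 of 20 fits, with a lowest permutation p of 0.00316 at a mean of at least 2 FPKM. The gene-list alternatives were not run, since no list could be matched. Few reads limit loci such as Glyma.17G235366.Wm82.a4.v1, which had 30 to 45 reads per OX5 library and where 3 reads are 1.57 FPKM. In the same libraries, 3 reads are 0.0372 FPKM at Glyma.19G026600.Wm82.a4.v1. The value of a read thus depends on gene length as well as on depth.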

Other observations

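The tests of other splits were chosen only after the results were seen. The 10 largest falls on the log2(FPKM + 1) scale were taken among changed genes with no overlap between the lines and at least 5 FPKM in the higher line. In 8 of the 10, OX5 replicate 3 was the highest OX5 library, and in 9 of the 10 the lowest was OX5 replicate 1 or 2. In 5 of the 10, WT replicate 1 was highest, WT replicate 3 second and WT replicate 2 lowest of the WT libraries, and in the other 5 they were not in that order. This WT order also occurred among the 10 largest rises, at Glyma.04G227900.Wm82.a4.v1 and Glyma.09G041900.Wm82.a4.v1, so it is not particular to falls. The share of all genes with these orders was not counted. Among fallen neighbours, the run of 3 loci on chromosome 9 had log2 fold changes from −1.72 to −1.04. On chromosome 20, the locus at 0 reads in every WT library and the tested locus before it both rose, with log2 fold changes between 0.87 and 1.98.

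The labelled lines gave far more changed genes than any other split of the libraries, which by itself cannot exclude chance. Of the 35 splits of the 8 libraries into 4 and 4, only the real one gave as many as 729 genes, and the highest other split gave 1. For changes of at least 2-fold, the real split gave 369 and the highest other split 1, so that again 1 of 35 splits was as large. A share below 1 in 35 cannot be reached with these splits. The other splits mix the lines, so a difference between the lines itself leaves them few calls. The libraries of a line may also not be separate plants.

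The order of the deposited table carries information on the comparison. A row without a gene name follows the first 2452 genes, and 717 of the 729 calls lie above it and 12 below. Of the tested genes above it, 98.5% had an unadjusted limma p under 0.05, against 15.1% below it. Of the genes above it, 1236 were higher and 1216 lower in OX5 by mean FPKM. Over all tested genes, row position and limma p had a Spearman rho of 0.925 across genes, which are not independent replicates.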
